A study of Mus musculus with 2 samples.

How the data were processed

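The series holds 2 droplet single-cell RNA libraries, 1 per group, from brains of mice aged 18 months on the C57BL/6J background. Per the labels, one library is of wild-type mice (WT) and the other of mice lacking CD200R1 (KO), an inhibitory receptor of myeloid cells, and the genotype was not checked here. Per the labels' protocols, the mice were untreated, the perfused brains were dissociated with a commercial kit, and CD11b-positive cells were taken with magnetic particles before 10x Chromium 3′ v3.1 library preparation. The number of mice behind each library is not stated. The study title names Parkinson's disease, while the labels give no disease model or treatment to these mice.

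The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger 7.0.1 per the file headers. Alignment with STAR to GRCm38/mm10 and a use of Seurat 3.1.1 are named in the submitters' processing notes, with no parameters. Each matrix lists 32285 genes. The barcodes numbered 18228 and 19159 in the libraries labelled WT and KO, which are the cell numbers stated by the study, and none held under 500 UMIs. Gene positions were taken from GENCODE vM21 (GRCm38) and are 1-based. The annotation release behind the deposited counts is not stated.

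Cells were kept with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs. This left 16601 and 17659 cells in the libraries labelled WT and KO. Mitochondrial share removed 1622 and 1495 barcodes, and the gene minimum 14 and 13. Doublets were called per library with Scrublet at its automatic threshold, with an expected rate of 0.8% per 1000 barcodes. The calls removed 270 cells (1.63%) labelled WT and 659 cells (3.73%) labelled KO, below the expected 13.3% and 14.1%, so doublets remain. The final sets held 16331 and 17000 cells.

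Counts were scaled to 10000 per cell and logged. Both libraries were clustered together without integration on 2000 variable genes (without sex-linked genes, Cd200r1 and mitochondrial genes), 30 principal components, 15 neighbours and Leiden resolution 1. Clusters were named "X-like" from marker lists, with at least 3 markers detected in 25% of the cluster's cells at a log2 fold of at least 1. The marker lists, the 26 gene lists, the filters, the rule for named genes and the alternatives not marked otherwise below were fixed before the data were examined. A cluster was left unnamed where its leading genes held more markers of other classes than of its own. Leading genes were taken against all other cells and against clusters of other classes, and this rule left clusters 18 and 24 unnamed. The following 4 details were set after the data were seen, and 8 clusters stayed unnamed in all. A cluster with low UMI counts against either library and no own marker among its top genes was left unnamed, a cluster with markers of a second class at a share of at least 0.5 of the first was left unnamed, a state needed its own markers, and core sub-clusters were defined for a check on mixed cells. The unnamed clusters held 33.3% of cells labelled WT and 25.0% of cells labelled KO. The largest were cluster 1, with microglial markers at a median of 1275 UMIs (13.3% and 9.94%), and cluster 3, at a median of 751 UMIs (12.2% and 8.66%). Cluster 8, with mural and endothelial markers, held 2.43% and 4.01%. Clusters 18, 19, 20, 24 and 30 held 1.56%, 0.661%, 1.73%, 1.33% and 0.0918% of cells labelled WT, against 0.706%, 1.18%, 0.135%, 0.135% and 0.218% of cells labelled KO.

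UMIs were summed per library and class, and 11 classes with at least 50 cells in each library were compared. The value per gene was the log2 ratio of CPM in the library labelled KO to CPM in the library labelled WT, each plus 10 CPM. List members needed 20 UMIs over both libraries and counted as higher or lower at a ratio of at least 1.25. Genes differing at least 2-fold were counted among those with at least 50 UMIs. The named genes are the 10 highest and 10 lowest such genes in the microglia, CNS-associated macrophage and T cell classes and 5 each way in the others. That ranking leaves out mitochondrial, ribosomal, haemoglobin and sex-linked genes, immunoglobulin and T cell receptor variable segments, predicted genes named Gm or Rik, Cd200r1 and markers of another class. Up to 2 members at each end of a fixed list are named as well. Each list median was placed among 10000 random lists of the same size matched on mean expression, a description of these 2 libraries.

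With 1 library per group no test between genotypes was possible, and no p-value is given. Intervals are 95%, exact Poisson for UMI sums and exact Clopper-Pearson for shares, and cover counting error only. The list median was made the leading value of a list after both the medians and the member counts had been computed. Under the alternatives the counts moved in 126 of 739 cases and reversed in 4. Lists of glucocorticoid-induced, clock and rRNA-linked genes, and the follow-up of single genes, were chosen after their values were seen.

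The gene and list steps were tested on simulated counts with Poisson noise only, drawn from the gene proportions pooled over both libraries, with 200 genes changed. Among 14083 genes simulated for microglia, the 2-fold threshold recovered 0% of genes changed 1.5-fold, 45.5% of those changed 2.5-fold and 60.3% of those changed 4-fold. The same shares were 0%, 37.9% and 82.5% among 11352 genes for CNS-associated macrophages, and 0%, 66.7% and 96.8% among 6965 genes for T cells. At most 1 unchanged gene passed in these 3 classes, and 5 passed among 3944 genes simulated for B cells. Of 500 unchanged lists, 93% (microglia), 94.2% (CNS-associated macrophages) and 95% (T cells) fell within the central range of the random lists.

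The alternatives were a stricter filter (800 genes, 1500 UMIs, 5% mitochondrial) or none, doublets kept, Leiden resolutions 0.5 and 2, TMM scaling (edgeR 4.0.16), pseudocounts of 1 and 50 CPM, the mean of per-cell CPM, and cells thinned to 1 depth per class. Others were a gene minimum of 200 UMIs, no minimum for list members, and resolutions 0.3 and 1 for states. Thinning to 5260 UMIs left out 737 and 1160 microglia-like cells of the libraries labelled WT and KO. The corresponding losses were 175 and 242 CNS-associated macrophage-like cells and 30 and 83 T cell-like cells. Core sub-clusters alone, shares among named immune cells and the low-UMI cluster counted as microglia were added after seeing the data. Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used. Splicing, variants and reads were not analysed here.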

Results

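Single-cell expression was measured in CD11b-selected brain cells of aged mice, in 1 library labelled WT and 1 labelled KO for the inhibitory receptor CD200R1. The libraries held 127429919 and 131196245 UMIs. The median barcode had 3596.5 UMIs and 1698 genes in the library labelled WT, against 3975 UMIs and 1879 genes in the library labelled KO. There are no replicates, so every difference below is between 2 libraries and has no replicate check, and intervals cover counting error only.

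Over all kept cells the targeted gene was at a similar level in both libraries, while it was lower in the macrophage and microglia classes and higher in the T cell class of the library labelled KO. Cd200r1 (ENSMUSG00000022667, GRCm38 chromosome 16, 44765736 to 44794978, plus strand, 7 exons) had 1460 UMIs in kept cells of the library labelled WT, or 12.7 CPM (12.0 to 13.3). The library labelled KO had 1395 UMIs, or 12.0 CPM (11.3 to 12.6), a ratio of 0.943 (0.876 to 1.02). By class the ratio was 0.907 (0.825 to 0.997) in microglia-like cells and 0.667 (0.556 to 0.802) in CNS-associated macrophage-like cells. It was 1.98 (1.37 to 2.91) in T cell-like cells. Markers of CNS-associated macrophages in T cell-like cells were at a ratio of 2.11 (1.69 to 2.63). The unnamed part of the macrophage class, which includes sub-clusters with microglial markers, held 37.3% of it in the library labelled WT and 44.9% in the library labelled KO. Mixed cells and free RNA were not separated from these class ratios. The deleted exons are not given, the last exon begins at 44794200, and a 3′ tag outside the deleted part checks nothing, so the labels were not checked by this gene and directions below follow the labels as given. Of the related receptors, Cd200r4 had 2.94 and 3.38 CPM, Cd200r3 0.339 and 0.411 CPM and Cd200r2 0.208 and 0.103 CPM (24 and 12 UMIs) in the libraries labelled WT and KO. Cd200, the ligand, had 235 CPM (232 to 238) over all kept cells of the library labelled WT and 162 CPM (160 to 164) over those of the library labelled KO. Differences in the make-up of the libraries were not separated from these Cd200 levels. Both libraries carried Y-linked transcripts, with Ddx3y at 87.1 and 85.8 CPM and 11 and 13 UMIs of Xist.

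The study asks about macrophages at the brain's borders and T cells, so the make-up of the selected cells was compared first. CNS-associated macrophage-like cells, named from markers such as Mrc1, F13a1, Cd163 and Ms4a7, made up 3.97% (3.67 to 4.28) of cells labelled WT and 6.01% (5.65 to 6.37) of cells labelled KO, a ratio of 1.51. The class mixes in sub-clusters 0 and 1, with microglial markers at 0.810 and 0.934 of the microglial level, and its core sub-clusters alone held 2.38% and 3.12%, a ratio of 1.31. With no filter on cells the class held 2.31% and 2.89%, a ratio of 1.254. T cell-like cells, named from markers such as Cd3g, Cd3d, Trbc2 and Skap1, made up 1.23% (1.07 to 1.41) and 1.46% (1.29 to 1.66), and the interval of their ratio, 0.984 to 1.44, includes equal shares. The class holds sub-cluster 3 (19 and 23 cells), led by NK genes such as Klra8 and Ncr1. It also holds sub-clusters 4 (18 and 15 cells) and 5 (12 and 15 cells), with microglial and endothelial markers. Its core sub-clusters alone held 0.931% and 1.15%. Neutrophil-like cells were at 1.08% and 0.524%, a ratio of 0.483 (0.370 to 0.627). B cell-like cells were at 0.870% and 0.453%, a ratio of 0.521 (0.389 to 0.692). Other blood signals were also lower in the library labelled KO. Cluster 20, with the platelet genes Ppbp, Pf4 and Gp9 among its leading genes, held 1.73% and 0.135%. Cluster 24, with Ppbp and Hba-a1 among its leading genes, held 1.33% and 0.135%. It also carried 8 endothelial markers, with Ly6c1 and Cldn5 among its leading genes, and as an unnamed cluster it is not counted in the endothelial-like class. Erythroid markers were at 1706 and 12.8 CPM in mural-like and 1489 and 719 CPM in endothelial-like cells, and residual blood was not separated from the shares. Microglia-like cells made up 21.6% (21.0 to 22.3) and 23.9% (23.3 to 24.6). That order turned under the stricter filter (ratio 0.966), among named immune cells (0.983) and with the low-UMI cluster counted as microglia (0.970). The intervals of these ratios include equal shares. All of these shares were measured after magnetic CD11b selection, which enriches myeloid cells to an unknown degree.

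Cells outside the myeloid target of the selection were abundant. Endothelial-like cells made up 16.4% and 16.0%, mural-like cells 8.59% and 8.05%, and astrocyte-like cells 5.96% and 7.61% of the CD11b-selected cells labelled WT and KO. Ependymal or choroid plexus-like cells made up 4.28% and 7.61%, with cluster 10 the largest part in the library labelled WT (420 of 699 cells) and cluster 11 in the library labelled KO (697 of 1294). Fibroblast-like cells were at 1.49% and 1.88%, and monocyte-like cells at 0.729% and 0.776%. Dendritic cell-like (30 and 45 cells), oligodendrocyte-like (30 and 66) and erythroid-like cells (18 and 13) were too few to compare.

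**Figure D1:**
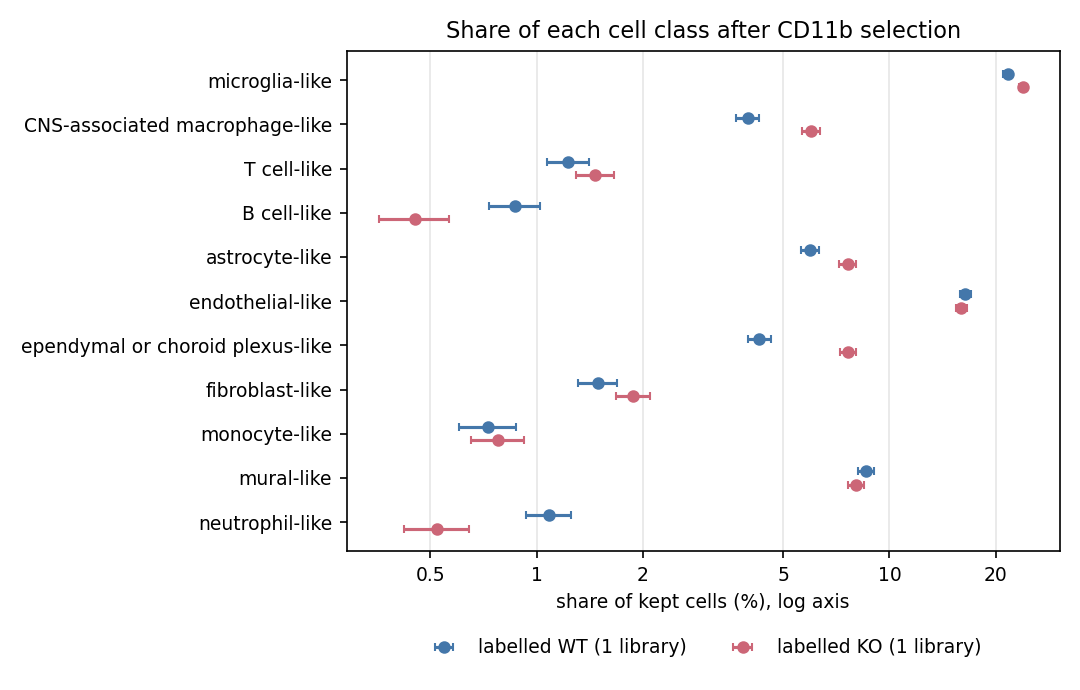
Share of kept cells per class in percent for the libraries labelled WT and KO, with exact 95% binomial intervals for counting error. CNS-associated macrophage-like cells stand at 3.97% and 6.01%, and neutrophil-like cells at 1.08% and 0.524%.

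Genes of the type I interferon response, which cells switch on after sensing interferon, were higher in the library labelled KO in every one of the 11 classes. The list's median log2 ratio was 1.26 in microglia-like cells, where 21 of 22 measured members passed the list threshold as higher and 0 as lower. It was 0.74 in CNS-associated macrophage-like cells (21 of 22 higher) and 0.96 in T cell-like cells (22 of 22 higher). In the other classes the medians ran from 0.82 in mural-like cells to 1.87 in monocyte-like cells, with 1.31 in endothelial-like and 1.81 in neutrophil-like cells. Each of the 3 main medians lay at percentile 100 of the random lists. With a pseudocount of 50 CPM they were 0.75, 0.52 and 0.57.

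**Figure D2:**
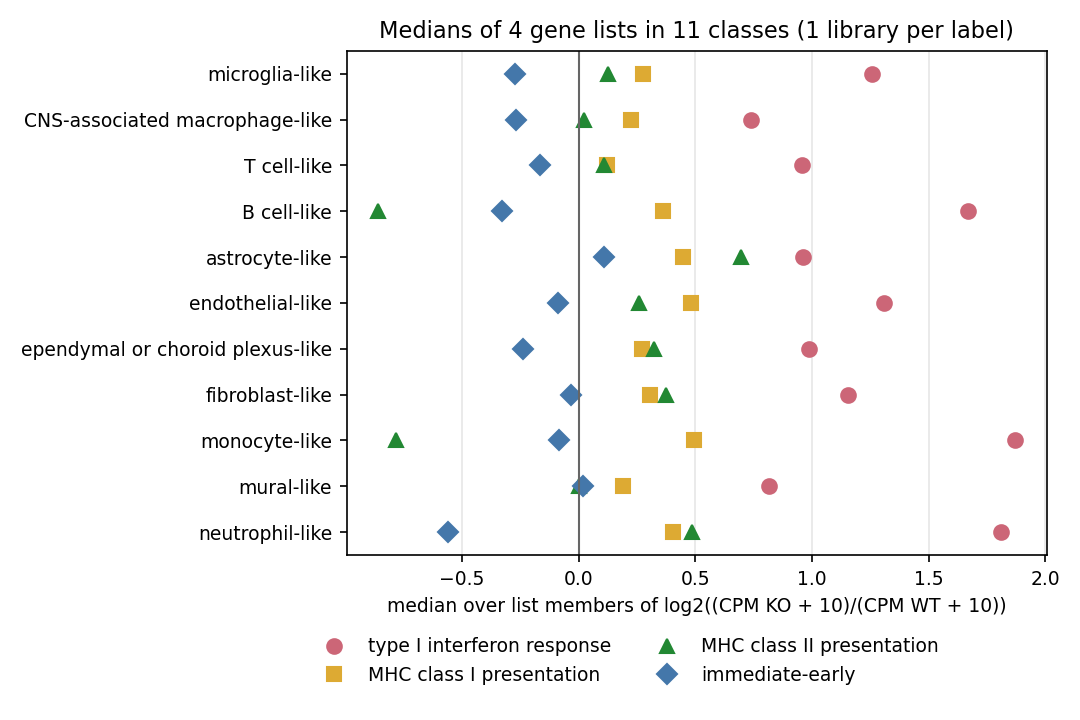
Median log2 ratio (library labelled KO to library labelled WT) of the type I interferon, MHC class I, MHC class II and immediate-early lists in each class compared. The type I interferon list stands at 1.26, 0.74 and 0.96 in microglia-like, CNS-associated macrophage-like and T cell-like cells, above the other lists drawn.

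In microglia-like cells the interferon-induced Rtp4 went from 20.1 CPM (18.7 to 21.5) in the library labelled WT to 129 CPM (126 to 133) in the library labelled KO, and Ifi27l2a from 121 to 578 CPM. The list's lowest members were Rsad2 (log2 ratio 0.53) and Ifi44 (0.28, at 0.868 and 3.15 CPM). MHC class I presentation had a median of 0.28 with 6 of 16 members higher, led by Nlrc5, a transactivator of these genes (12.4 to 29.8 CPM), and the proteasome activator Psme2 (82.5 to 124 CPM). H2-D1 and Tap2 stood at 0.098 and 0.087. MHC class II presentation had a median of 0.13, with H2-Eb1 (0.41) and H2-Aa (0.32) higher, Ciita at -0.023 and H2-DMb2 at -0.072. Complement and Fc receptors had a median of 0.074, with Fcgr1 (0.45) and Fcgr4 (0.33) higher and C5ar1 lower (-0.33).

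Some inflammatory and stress-response genes of microglia-like cells were lower in the library labelled KO, while most members of these lists lay within the list threshold. The NFkB and inflammatory cytokine list had a median of -0.13 with 2 of 18 members lower, Tnf (175 to 124 CPM) and Il1b (56.4 to 30.7 CPM). Of 17 chemokines, 4 were higher and 3 lower around a median of -0.034. Cxcl9 (0.65) and Ccl8 (0.53) were highest, and Ccl3 (1055 to 604 CPM) and Ccl4 (1913 to 1231 CPM) lowest. The immediate-early list, which responds to cell dissociation, had a median of -0.27 with 9 of 22 members lower, among them Hspa1b (193 to 110 CPM) and Ier2 (220 to 139 CPM), while Fos stood at 0.22. The disease-associated list, of genes seen in microglia near pathology, had a median of -0.16 with 3 of 19 members lower, including Lpl (-0.58) and Spp1 (-0.55), and Tyrobp at 0.13. Its median turned to 0.057 under the stricter filter on cells.

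The other lists moved little in microglia-like cells. Medians were 0.016 for homeostatic genes (Olfml3 0.24, P2ry13 -0.18), 0.11 for oxidative phosphorylation, -0.10 for glycolysis and hypoxia, 0.038 for lysosome and phagocytosis and -0.011 for lipid and cholesterol. They were -0.037 for inhibitory receptors (Lilrb4a -0.47), -0.077 for CD200R signalling, -0.059 for TGFb and IL10, 0.036 for Parkinson disease genes (Pink1 0.17), -0.061 for costimulation and adhesion (Lgals9 0.34, Tnfsf9 -0.27) and -0.072 for cell cycle. The chemokine and lipid medians changed sign under at least 1 alternative. No member of the homeostatic, Parkinson or oxidative phosphorylation lists passed that threshold.

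Among 14102 genes of microglia-like cells, 27 were at least 2-fold higher and 2 at least 2-fold lower. These counts were 75 and 17 with a pseudocount of 1 CPM and 6 and 0 with 50 CPM. The 10 highest were Rtp4, Ifi27l2a, Oasl2, Slfn2, Xaf1, Slfn5, Isg15, Ifitm3, Npl and Ifit3, of which Npl, an enzyme of sialic acid breakdown, went from 79.4 CPM (76.7 to 82.3) to 228 CPM (224 to 233). The 2 genes past 2-fold lower were Zbtb16, a transcription factor gene induced by glucocorticoids (36.1 to 7.40 CPM), and Slc15a2, a peptide transporter (604 to 53 UMIs, log2 ratio -1.17). Also among the 10 lowest were Mmp12 (-0.96), Fkbp5, another glucocorticoid-induced gene (691 to 359 CPM), Ccl3, Lars2, Hspa1b, Il1b, Cables1 and Thap8, the last at -0.69. Choroid plexus markers, which these cells should lack, were at 1963 CPM in microglia-like cells labelled WT and 3025 CPM in those labelled KO.

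**Figure D3:**
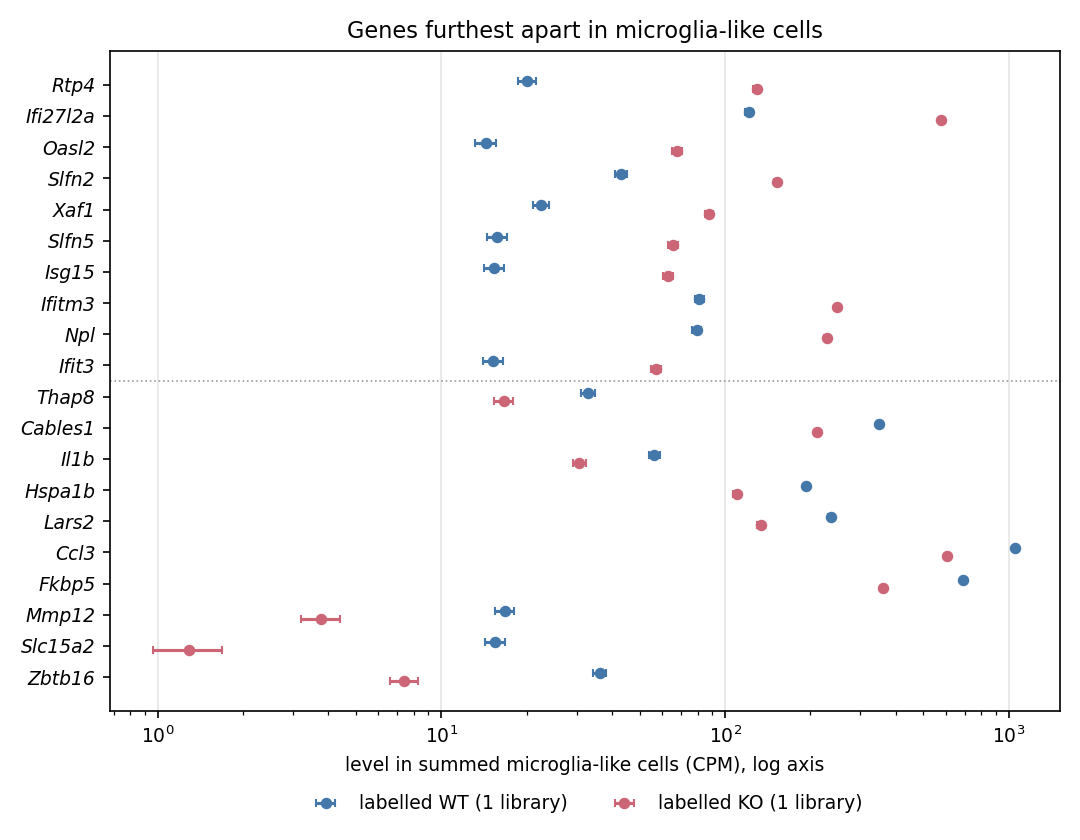
Level in CPM of the 10 highest and 10 lowest named genes in summed microglia-like cells of the libraries labelled WT and KO. Intervals are exact Poisson and cover counting error only. Rtp4 stands at 20.1 and 129 CPM and Zbtb16 at 36.1 and 7.40 CPM. The log2 ratios (library labelled KO to library labelled WT) computed from these levels are 2.21 and -1.41.

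A disease-associated microglia-like state, named from genes such as Spp1, Lpl and Apoe, held 7.10% (6.28 to 8.0) of microglia-like cells labelled WT and 3.81% (3.24 to 4.44) of those labelled KO, within the magnetic CD11b selection. Its markers differed between the libraries inside the state, with a median log2 ratio of 0.23 and a range of -0.29 to 1.54. Cycling microglia-like cells were at 0.509% and 0.418% (18 and 17 cells). The size of the interferon-responsive cluster is not read as a difference in state, since its defining genes differ between the libraries.

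CNS-associated macrophage-like cells had higher interferon genes and lower border-macrophage genes in the library labelled KO. The core macrophage list had a median of -0.46 with 13 of 18 members lower, among them Wfdc17 (614 to 320 CPM) and Lyve1 (130 to 67.9 CPM). That median was -0.10, with 6 of 18 members lower, in the core sub-clusters (388 and 530 cells), which leave out the sub-clusters highest in microglial markers and keep others at 0.203 to 0.363 of the microglial level. Microglial markers summed to 9271 CPM in the whole class labelled WT and 11173 CPM in the class labelled KO, erythroid markers to 289 and 7.28 CPM, and endothelial markers to 457 and 245 CPM. MHC class I presentation had a median of 0.22 with 5 of 16 members higher, led by Psme1 (217 to 310 CPM). MHC class II presentation had a median of 0.021, with H2-Ob at 0.41 and Cd74 at -0.28.

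Chemokine genes went both ways in these macrophages, with 2 of 17 higher, 5 lower and a median of -0.085. Ccl2, a monocyte attractant, went from 357 to 174 CPM and Ccl24 from 150 to 75.9 CPM, while Cxcl2 stood at 0.42. The adhesion gene Vcam1 (517 to 283 CPM) and Tnfsf9 (-0.73) were lowest of the costimulation list (median -0.062). Ccl2 and Ccl24 are among the leading genes of sub-cluster 5 and Vcam1 of sub-cluster 2, each named Lyve1-high. The unnamed part of the class, which includes sub-clusters 0 and 1 with microglial markers, held 37.3% (WT) and 44.9% (KO). A shift in make-up was not separated from these differences. The immediate-early list had a median of -0.27 with 8 of 22 members lower, led by Hspa1a (277 to 157 CPM). Further medians were -0.072 for NFkB and cytokines, 0.12 for complement and Fc receptors (Fcgr1 0.58), 0.033 for lysosome (Ctss 0.40, Cd36 -0.75), -0.066 for lipid (Pparg -0.88, Lpl -0.78) and 0.11 for oxidative phosphorylation. The rest were -0.085 for glycolysis (Slc2a1 -0.58), -0.087 for inhibitory receptors (Lilrb4a -0.54), -0.13 for CD200R signalling (Cd200 -0.81, with a ratio of 0.660 and an interval of 0.371 to 1.16 in the core sub-clusters), -0.039 for TGFb and IL10, -0.034 for Parkinson disease genes and -0.026 for cell cycle. With no filter on cells the chemokine and lipid medians turned to 0.088 and 0.047, and the glycolysis median turned to 0.011 in the core sub-clusters and 0.026 with cells thinned to 1 depth. Medians of the MHC class II, costimulation, NFkB, lysosome, TGFb and IL10, Parkinson and cell cycle lists also changed sign under at least 1 alternative.

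Among 11382 genes of these macrophages, 9 were at least 2-fold higher and 13 lower (37 and 95 with a pseudocount of 1 CPM, 1 and 4 with 50 CPM). Besides interferon-induced genes such as Rtp4, Ifi27l2a, Isg15, Oasl2, Ifit2, Lgals3bp and Eif2ak2, the highest included Npl (81.0 to 191 CPM) and Rasgrf2 (13.4 to 44.8 CPM). The lowest were Zbtb16 (140 to 35.9 CPM), the secreted phosphoprotein gene Spp1 (321 to 108 CPM), the growth factor gene Pdgfc (95.5 to 29.9 CPM), Egfr, Dpyd, Fkbp5 (733 to 349 CPM), Ccdc152, Mmp12, Ccl2 and Klf4. Of these, Pdgfc is a leading gene of Lyve1-high sub-cluster 2, and Egfr and Ccl2 of Lyve1-high sub-cluster 5. A shift in the make-up of the class was not separated from their values. Mmp12 stood at -1.01 in the class and at 0.011 in the core sub-clusters. Lyve1-high cells made up 30.2% (26.7 to 33.9) and 25.1% (22.4 to 27.9) of the class, and MHC-II-high cells 32.4% (28.8 to 36.2) and 30.1% (27.3 to 33.0), in the libraries labelled WT and KO after CD11b selection. At resolution 0.3 for states the MHC-II-high share was 15.4% and 15.9%, in the other order. At the main resolution the unnamed rest, which includes sub-clusters 0 and 1 with microglial markers, held 37.3% and 44.9%. Among the core sub-clusters alone, Lyve1-high cells were 196 of 388 cells labelled WT and 256 of 530 labelled KO. The MHC-II-high cells include sub-cluster 7 (18 and 33 cells), with monocyte genes such as Ly6c2 and Plac8 on top, and sub-cluster 4 (92 and 112 cells, median 1713.5 UMIs), led by Ptgds, Apod and Ttr.

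In T cell-like cells, genes of naive and recirculating T cells were lower in the library labelled KO. All 9 measured members were lower, with a median of -0.78, from Il7r (-0.36) and Tcf7 (-0.64) to S1pr1, the receptor for exit from tissue (176 to 82.8 CPM), and Klf3 (140 to 63.9 CPM). In core sub-clusters (152 and 196 cells) 8 of 9 were lower with a median of -0.86. The tissue residency list had a median of 0.19 with 4 of 12 higher, led by Xcl1 (126 to 231 CPM), and checkpoint and exhaustion genes 0.16 with 4 of 12 higher, led by Tox (501 to 767 CPM). Helper and regulatory genes had a median of 0.21 (Ikzf2 0.79, Icos -0.42) and activation genes 0.052 (Tnfrsf4 1.20). Cytotoxic effector genes had a median of 0.063 (Klrg1 0.75, Gzmk 0.64, Klrd1 -0.25), and -0.19 in core sub-clusters and -0.32 with cells thinned to 1 depth. Cell cycle genes had a median of -0.40 with 8 of 14 lower, such as Ube2c (42.1 to 11.8 CPM), and a median of 0.14 with cells thinned to 1 depth. A cycling T cell-like state was named only at resolution 1 for states, with 4 cells labelled WT (1.99%) and 4 labelled KO (1.61%).

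Several lists of myeloid genes were also higher in T cell-like cells labelled KO. Complement and Fc receptors had a median of 0.34 (C1qc 435 to 795 CPM), lysosome genes 0.35 (Lyz2 112 to 410 CPM), chemokines 0.33 (Ccl12 1.37) and the NFkB list 0.25 (Il1b 0.79). Markers of CNS-associated macrophages in these cells were at 86.9 and 183 CPM, of microglia at 1782 and 2298 CPM, and of choroid plexus at 3038 and 6039 CPM, in the libraries labelled WT and KO. Those of monocytes were at 1026 and 691 CPM, of dendritic cells at 84.9 and 52.1 CPM and of neutrophils at 81.6 and 82.8 CPM. With cells thinned to 1 depth the medians were -0.12 for complement and -0.24 for chemokines, and the chemokine median was -0.18 in the core sub-clusters. The lysosome median stayed positive but fell with cells thinned to 1 depth and under the stricter filter, and rose with no filter. Other medians were 0.12 for MHC class I, 0.11 for MHC class II, 0.11 for costimulation (Vcam1 -1.48), -0.17 for immediate-early genes (Atf3 0.84, Hspa1a -0.77), 0.10 for lipid (Apoe 1.44) and 0.093 for oxidative phosphorylation. The remaining ones were -0.018 for glycolysis, 0.19 for inhibitory receptors (Lilrb4a 0.97), 0.14 for CD200R signalling (Cd200r1 0.80), 0.13 for TGFb and IL10 (Tgfbr1 0.91) and 0.051 for Parkinson disease genes. The immediate-early median turned to 0.012 with no filter and 0.048 with doublets kept. Under the stricter filter the TGFb and IL10 median turned to -0.021 and the MHC class II median to -0.58. Medians of the costimulation, activation, glycolysis and CD200R signalling lists also changed sign under at least 1 alternative.

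Among 6986 genes of T cell-like cells, 22 were at least 2-fold higher and 24 lower (59 and 75 with a pseudocount of 1 CPM, 3 and 2 with 50 CPM). The highest were Dscam (4 and 62 UMIs), Lyz2, Isg15 (49.5 to 180 CPM), Ifi44, Usp18, Apoe (840 to 2293 CPM), Ccl12, Ifit1, Apobec1 and Trat1, an adaptor of the T cell receptor (20.7 to 65.5 CPM). The lowest were Gkn3 (159 to 47.3 CPM), Vcam1, Pdgfd, Ltbp4, Mgp, Ube2c, Nebl, Fbxl7, Cdkn1a and Ccdc85a. Endothelial markers were at 2663 and 1907 CPM in this class. In the core sub-clusters Pdgfd, Ltbp4, Mgp, Nebl, Fbxl7 and Ccdc85a stood between 0.063 and 0.36. CD8 cells made up 58.7% (51.6 to 65.6) and 54.2% (47.8 to 60.5) of T cell-like cells, and CD4 cells 16.9% (12.0 to 22.8) and 24.5% (19.3 to 30.3), in the libraries labelled WT and KO after CD11b selection. At resolution 1 for states CD8 cells were at 50.7% and 53.8%, in the other order.

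Classes outside the selection's target carried the interferon difference as well. Isg15 went from 125 to 693 CPM in endothelial-like cells, from 72.6 to 455 CPM in fibroblast-like cells and from 44.5 to 146 CPM in mural-like cells. Among the 8 other classes, MHC class I medians ran from 0.19 to 0.49. MHC class II medians ran from -0.86 in B cell-like cells to 0.70 in astrocyte-like cells, where H2-Eb1 went from 19.6 to 73.7 CPM. In the same astrocyte-like cells, marker ratios were 1.27 for microglia, 1.43 for dendritic cells and 1.45 for monocytes, but 1.0 for CNS-associated macrophages, 1.01 for neutrophils and 1.04 for plasmacytoid dendritic cells. In B cell-like cells plasma cell markers were at 6627 and 20215 CPM. With cells thinned to 1 depth the lowest MHC class II median was -1.74, and at Leiden resolution 2 the highest was 1.06. The ranges were -0.54 to 0.38 for costimulation, -0.32 to 0.41 for chemokines, -0.51 to 0.18 for NFkB, -0.56 to 0.11 for immediate-early genes and -0.045 to 0.42 for complement. They were -0.082 to 0.33 for lysosome, -0.39 to 0.097 for lipid, -0.22 to 0.42 for oxidative phosphorylation, -0.32 to 0.034 for glycolysis and -0.26 to 0.33 for inhibitory receptors. For CD200R signalling, TGFb and IL10, Parkinson disease genes and cell cycle they were -0.33 to 0.22, -0.50 to 0.41, -0.17 to 0.095 and -0.15 to 1.20. The highest TGFb and IL10 median was 0.17 with cells thinned to 1 depth and 0.092 with the mean of per-cell CPM. Cell cycle medians ran from -1.05 to 0.40 under the stricter filter. An end of the range moved by over 1.5 times under at least 1 alternative for every list here, and under the stricter filter the highest medians were 1.58 for complement, 0.93 for inhibitory receptors, 0.64 for lysosome, 0.32 for NFkB and 0.31 for immediate-early genes. The lowest complement median was -0.35 with no filter, and with the mean of per-cell CPM the highest NFkB median was -0.010 and the highest for inhibitory receptors 0.012.

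The counts of genes at least 2-fold higher and lower were 51 and 144 in B cell-like, 36 and 49 in astrocyte-like, 38 and 8 in endothelial-like and 25 and 10 in ependymal or choroid plexus-like cells. They were 41 and 45 in fibroblast-like, 103 and 23 in monocyte-like, 22 and 7 in mural-like and 89 and 90 in neutrophil-like cells. In endothelial-like cells Isg15, Ifit3, Irf7, Ifit1 and Ifi44 were highest, and Aldh1a1, Ifi213, Ifi203, Mndal and Fkbp5 lowest, with Ifi203 at 195 and 79.4 CPM. In monocyte-like cells Irf7 (20.9 to 299 CPM), Slfn4, Ifi27l2a, Oas3 and Isg15 were highest, and Prss34, H2-Aa (180 to 39.4 CPM), Csf1, H2-Ab1 and Zbtb16 lowest. In neutrophil-like cells Prss34, Ifi27l2a, Isg15, Ifit3 and Rsad2 were highest, and Wfdc17, Cxcl9, Il1b (1031 to 264 CPM), Itga4 and Cstdc5 lowest. The basophil protease gene Prss34 had 238 and 0 UMIs in monocyte-like cells but 1 and 407 UMIs in neutrophil-like cells. Mast cell or basophil markers went the same ways, at 221 and 23.8 CPM in monocyte-like and 13.5 and 237 CPM in neutrophil-like cells. Mixed cells were not separated from the Prss34 values.

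In B cell-like cells the light-chain gene Iglc1, Ifi27l2a, Isg15, Lyz2 and Top2a were highest, and the heavy-chain gene Ighg2c (4320 and 18 UMIs), Csn3, Spock2, Pgap1 and Pglyrp1 lowest. Spock2 and Pglyrp1 are also leading genes of endothelial-like clusters, and endothelial markers in B cell-like cells were at 998 and 306 CPM. In astrocyte-like cells Lrrtm4, Ifi27l2a, Irf7, H2-Eb1 and Rtp4 were highest. The lowest there, Sag (135 to 5.43 CPM), Chgb, Gnb3, Cngb3 and Otx2os1, include photoreceptor and pineal genes. In ependymal or choroid plexus-like cells Ifi27l2a (51.3 to 472 CPM), Gpx3, Isg15, Rtp4 and Ifit1 were highest, and Il1r1, Apoc1, Igfbp3, Lysmd4 and Plvap lowest. In fibroblast-like cells Igkc, Retnla, Isg15, Ccl8 and Ifit1 were highest, and Asic2, Tnc, Esm1, Pdzrn4 and Fanci lowest. Plasma cell markers in fibroblast-like cells were at 7.87 and 81.0 CPM in the libraries labelled WT and KO. In mural-like cells, where cluster 9 was largest in the library labelled WT and cluster 13 in the library labelled KO, Ifit1, Ifi27l2a, Isg15, Rtp4 and Actg2 were highest, and Angptl4, Sorcs1, Ccl5, Ccl3 and Fam13a lowest.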

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

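All tests in this part were chosen after the results were seen. Type I interferon genes were higher in the library labelled KO in all 11 classes, with medians from 0.74 to 1.87. Scaling by total UMIs was excluded as the sole cause, since the list lay at least 0.735 above the median of all genes in each class. Free RNA from 1 source in every droplet was excluded as the sole cause, because a member's share of the extra CPM differed by a median of 3.315 times over 4 classes. Animals, cages or preparation rather than genotype may also account for it, and with 1 library per group this stays open.

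Fkbp5 and Zbtb16 were lower in the library labelled KO in all 11 classes, with log2 ratios from -1.53 to -0.42 for Fkbp5 and -1.71 to -0.71 for Zbtb16. Less dissociation stress may contribute and stays open, with immediate-early medians lower in 9 of 11 classes and 0 classes higher past the random lists. Another time of day at collection may contribute and was not resolved, with clock output medians below -0.1 in 5 classes and above 0.1 in 1 class. Libraries from animals taken at a recorded hour would bear on the time of day only. Animals or preparation rather than genotype also stay open, with 1 library per group.

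Cd200r1 was at a ratio of 0.943 over all kept cells, with 0.907 in microglia-like, 0.667 in CNS-associated macrophage-like and 1.98 in T cell-like cells. Markers of CNS-associated macrophages were at a ratio of 2.11 in T cell-like cells, and mixed cells were not separated from the class ratios. The 3′ tag may lie outside the deleted part, which the ratio of 0.9429 leaves open while the deleted exons are not given. An exchange of the 2 labels may be considered, but the reverse ratio of 1.061 shows no loss in the library labelled WT either, so this gene does not tell the labels apart. Reads over each exon would decide, and they were not analysed here.

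MHC class II presentation had medians of -0.86 in B cell-like, 0.70 in astrocyte-like, 0.37 in fibroblast-like, -0.78 in monocyte-like and 0.49 in neutrophil-like cells, beside plasma cell markers at a ratio of 3.05 in B cell-like and microglia markers at 1.27 in astrocyte-like cells, and the difference was not tested. T cell costimulation and adhesion had medians of 0.38 in B cell-like and -0.54 in neutrophil-like cells, and the difference was not tested. Its highest median over the other classes was 0.18 with cells thinned to 1 depth, 0.23 with a pseudocount of 50 CPM and 0.52 under the stricter filter. TGFb and IL10 genes had medians of 0.41 in astrocyte-like and -0.50 in neutrophil-like cells, the highest over the other classes being 0.17 with cells thinned to 1 depth and 0.092 with the mean of per-cell CPM, and the difference was not tested. Cell cycle genes had medians of -0.40 in T cell-like, 1.20 in B cell-like and 0.45 in monocyte-like cells, and the difference was not tested. The T cell-like median turned positive with cells thinned to 1 depth. The highest over the other classes was 0.40 under the stricter filter and 0.47 with the mean of per-cell CPM. Unnamed clusters 8, 19 and 30 held 4.01%, 1.18% and 0.218% of kept cells of the library labelled KO after CD11b selection, while clusters 20 (283 and 23 cells) and 24 (217 and 23 cells) were smaller in that library, at ratios of 0.0781 and 0.102, and none was analysed further.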

How the results depend on the processing

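The values listed by setting below moved or reversed when that choice was changed, and every ratio is of the library labelled KO to the library labelled WT. The main values stand in the report. Values for the other classes' lists under changed settings, the core sub-clusters, the low-UMI cluster counted as microglia and shares among immune cells were chosen after seeing the data. A list median or share counts as reversed only where the counting interval of its main value excluded no difference, so other changes of sign stand among the moved or unchanged values. The intervals of the reversed shares under those alternatives include equal shares. Of 739 list medians under alternatives, 103 moved and 12 reversed. Of 680 named gene values, 204 moved and 9 reversed, of 77 shares 12 moved and 3 reversed, and of 250 gene counts 94 moved. Higher medians of the type I interferon list held under all alternatives run, from 0.75 to 1.79 in microglia-like, 0.52 to 0.86 in CNS-associated macrophage-like and 0.57 to 1.07 in T cell-like cells. The targeted gene's ratio was 0.955 with no filter, within the interval of its main value. No paired analysis was possible because each group has 1 library. A larger pseudocount shrinks log ratios and a smaller one widens them by construction, and a minimum of 200 UMIs tests fewer genes. The causes of the other shifts were not tested.

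With the stricter filter on cells, the share ratio was 0.966 for microglia-like cells (reversed), 0.874 for endothelial-like cells, 1.58 for ependymal or choroid plexus-like cells and 1.08 for mural-like cells. List medians in microglia-like cells were 0.057 for disease-associated genes (reversed), 0.17 for MHC class II presentation, 0.32 for MHC class I presentation, 0.059 for chemokines, 0.072 for lysosome and phagocytosis, 0.0062 for lipid and cholesterol, 0.14 for oxidative phosphorylation and -0.022 for cell cycle. List medians in CNS-associated macrophage-like cells were 0.089 for lysosome and phagocytosis and -0.19 for cell cycle. List medians in T cell-like cells were -0.58 for MHC class II presentation, 0.15 for lysosome and phagocytosis, -0.021 for TGFb and IL10 (reversed) and -0.058 for cytotoxic effectors. Genes at least 2-fold higher numbered 244 in fibroblast-like cells and 69 in mural-like cells. Genes at least 2-fold lower numbered 53 in T cell-like cells, 223 in astrocyte-like cells, 36 in ependymal or choroid plexus-like cells, 172 in fibroblast-like cells, 30 in mural-like cells and 145 in neutrophil-like cells. Of the other classes, the list median was past the list threshold as higher in 2 for chemokines, 4 for complement and Fc receptors, 2 for lysosome and phagocytosis, 0 for oxidative phosphorylation, 2 for inhibitory receptors of myeloid cells and 1 for cell cycle. The cell cycle median was past it as lower in 2. Of the other classes, a list median past the list threshold as lower was found in 1 for immediate-early genes and 0 for lipid and cholesterol.

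With no filter on cells, the share ratio was 1.254 for CNS-associated macrophage-like cells, 1.09 for astrocyte-like cells and 0.912 for endothelial-like cells. In microglia-like cells the list medians were 0.095 for oxidative phosphorylation. In CNS-associated macrophage-like cells the list medians were 0.85 for type I interferon response, 0.088 for chemokines (reversed), 0.070 for NFkB and inflammatory cytokines, -0.23 for core macrophage genes, 0.15 for complement and Fc receptors, 0.069 for lysosome and phagocytosis, 0.047 for lipid and cholesterol (reversed), 0.081 for oxidative phosphorylation, 0.022 for TGFb and IL10 and 0.17 for cell cycle. In T cell-like cells the list medians were 0.61 for MHC class II presentation, 0.012 for immediate-early genes (reversed), 0.70 for complement and Fc receptors, 0.57 for lysosome and phagocytosis, 0.029 for oxidative phosphorylation, 0.49 for inhibitory receptors of myeloid cells, 0.32 for Parkinson disease genes and 0.092 for tissue residency. The genes 2-fold higher numbered 14 in CNS-associated macrophage-like cells and 49 in T cell-like cells. The genes 2-fold lower numbered 31 in CNS-associated macrophage-like cells, 4 in astrocyte-like cells and 1 in ependymal or choroid plexus-like cells. Among other classes, a median past the list threshold as higher was found in 2 for chemokines, 4 for complement and Fc receptors and 0 for TGFb and IL10. Medians past the list threshold as lower were found in other classes in 0 for lipid and cholesterol, 1 for complement and Fc receptors and 2 for TGFb and IL10.

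With called doublets kept, the share ratio was 0.9 for endothelial-like cells. For T cell-like cells, list medians stood at 0.40 for MHC class II presentation, 0.048 for immediate-early genes (reversed), 0.52 for lysosome and phagocytosis, 0.45 for inhibitory receptors of myeloid cells and 0.26 for Parkinson disease genes. At least 2-fold higher were 35 in T cell-like cells. At least 2-fold lower were 12 in T cell-like cells. Other classes with a median past the list threshold as higher numbered 4 for complement and Fc receptors, 0 for lysosome and phagocytosis and 0 for inhibitory receptors of myeloid cells. As lower they numbered 1 for complement and Fc receptors and 2 for TGFb and IL10.

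At Leiden resolution 0.5, the share ratio was 0.913 for endothelial-like cells. Of the other classes, the list median was past the list threshold as higher in 0 for inhibitory receptors of myeloid cells.

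At Leiden resolution 2, the share ratio was 1.15 for astrocyte-like cells and 0.920 for endothelial-like cells. For CNS-associated macrophage-like cells, list medians stood at 0.061 for lysosome and phagocytosis. Past 2-fold lower, the genes numbered 39 in CNS-associated macrophage-like cells and 21 in astrocyte-like cells. Among other classes, a median past the list threshold as higher was found in 0 for lysosome and phagocytosis.

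With TMM scaling, list medians in microglia-like cells were 0.0049 for homeostatic genes.

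With a pseudocount of 1 CPM, list medians in microglia-like cells were 1.79 for type I interferon response, -0.18 for NFkB and inflammatory cytokines, -0.14 for glycolysis and hypoxia and -0.26 for cell cycle. Medians in CNS-associated macrophage-like cells came to 0.86 for type I interferon response. Medians in T cell-like cells came to -0.57 for cell cycle and -1.0 for naive and recirculating genes. Past 2-fold higher, the genes numbered 75 in microglia-like cells, 37 in CNS-associated macrophage-like cells, 59 in T cell-like cells, 144 in astrocyte-like cells, 72 in endothelial-like cells, 133 in ependymal or choroid plexus-like cells, 104 in fibroblast-like cells and 100 in mural-like cells. Genes at least 2-fold lower numbered 17 in microglia-like cells, 95 in CNS-associated macrophage-like cells, 75 in T cell-like cells, 110 in astrocyte-like cells, 25 in endothelial-like cells, 54 in ependymal or choroid plexus-like cells, 102 in fibroblast-like cells, 62 in monocyte-like cells, 24 in mural-like cells and 243 in neutrophil-like cells. Other classes with a median past the list threshold as higher numbered 5 for MHC class II presentation and 2 for T cell costimulation and adhesion.

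With a pseudocount of 50 CPM, list medians in microglia-like cells were -0.086 for disease-associated genes, 0.75 for type I interferon response, 0.079 for MHC class II presentation, 0.21 for MHC class I presentation, -0.021 for T cell costimulation and adhesion, -0.083 for NFkB and inflammatory cytokines, -0.20 for immediate-early genes, 0.088 for oxidative phosphorylation, -0.069 for glycolysis and hypoxia and -0.018 for cell cycle. The medians in CNS-associated macrophage-like cells were 0.52 for type I interferon response, 0.17 for MHC class I presentation, -0.22 for immediate-early genes and -0.41 for core macrophage genes. The medians in T cell-like cells were 0.57 for type I interferon response, 0.22 for complement and Fc receptors and -0.64 for naive and recirculating genes. Genes at least 2-fold higher numbered 6 in microglia-like cells, 1 in CNS-associated macrophage-like cells, 3 in T cell-like cells, 19 in B cell-like cells, 2 in astrocyte-like cells, 13 in endothelial-like cells, 6 in ependymal or choroid plexus-like cells, 14 in fibroblast-like cells, 37 in monocyte-like cells, 2 in mural-like cells and 34 in neutrophil-like cells. The genes 2-fold lower numbered 0 in microglia-like cells, 4 in CNS-associated macrophage-like cells, 2 in T cell-like cells, 39 in B cell-like cells, 10 in astrocyte-like cells, 0 in endothelial-like cells, 0 in ependymal or choroid plexus-like cells, 5 in fibroblast-like cells, 7 in monocyte-like cells and 11 in neutrophil-like cells. Of the other classes, the list median was past the list threshold as higher in 1 for MHC class II presentation, 2 for MHC class I presentation, 0 for T cell costimulation and adhesion, 0 for chemokines, 0 for lysosome and phagocytosis, 0 for inhibitory receptors of myeloid cells, 0 for TGFb and IL10 and 1 for cell cycle. Other classes with a median past the list threshold as lower numbered 1 for immediate-early genes, 0 for lipid and cholesterol and 0 for CD200R signalling.

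With the mean of per-cell CPM, list medians in microglia-like cells were 0.039 for homeostatic genes, -0.10 for disease-associated genes, 0.32 for MHC class I presentation, -0.081 for NFkB and inflammatory cytokines, -0.23 for immediate-early genes, 0.064 for lysosome and phagocytosis, 0.010 for oxidative phosphorylation and -0.013 for TGFb and IL10. List medians in CNS-associated macrophage-like cells were 0.17 for MHC class II presentation, -0.19 for chemokines, -0.22 for immediate-early genes, -0.26 for core macrophage genes, -0.017 for lysosome and phagocytosis, 0.054 for oxidative phosphorylation and 0.0093 for Parkinson disease genes. List medians in T cell-like cells were 0.14 for complement and Fc receptors, 0.21 for lysosome and phagocytosis, 0.023 for oxidative phosphorylation, 0.082 for inhibitory receptors of myeloid cells, -0.033 for cell cycle and -0.22 for cytotoxic effectors. The genes 2-fold higher numbered 35 in T cell-like cells, 90 in B cell-like cells, 64 in astrocyte-like cells, 49 in ependymal or choroid plexus-like cells, 134 in fibroblast-like cells and 12 in mural-like cells. At least 2-fold lower were 10 in T cell-like cells, 11 in astrocyte-like cells, 5 in endothelial-like cells, 22 in ependymal or choroid plexus-like cells, 114 in fibroblast-like cells, 39 in monocyte-like cells and 181 in neutrophil-like cells. Among other classes, a median past the list threshold as higher was found in 0 for chemokines, 0 for complement and Fc receptors, 0 for lysosome and phagocytosis, 0 for oxidative phosphorylation, 0 for inhibitory receptors of myeloid cells, 0 for TGFb and IL10 and 1 for cell cycle. As lower it was found in 1 for inhibitory receptors of myeloid cells and 2 for TGFb and IL10. Of the other classes, a list median past the list threshold as lower was found in 1 for immediate-early genes and 0 for lipid and cholesterol.

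With cells thinned to 1 depth, list medians in microglia-like cells were 0.31 for MHC class I presentation, -0.0099 for T cell costimulation and adhesion, 0.020 for chemokines, -0.31 for immediate-early genes and 0.023 for complement and Fc receptors. In CNS-associated macrophage-like cells the list medians were 0.67 for type I interferon response, -0.35 for core macrophage genes, -0.21 for lipid and cholesterol, 0.026 for glycolysis and hypoxia (reversed) and -0.11 for cell cycle. In T cell-like cells the list medians were 1.07 for type I interferon response, -0.24 for chemokines (reversed), -0.12 for complement and Fc receptors (reversed), 0.098 for lysosome and phagocytosis, 0.14 for cell cycle (reversed) and -0.32 for cytotoxic effectors. Members higher numbered 1 of chemokines in T cell-like cells (reversed) and 3 of complement and Fc receptors in T cell-like cells (reversed). Members lower numbered 0 of cell cycle in T cell-like cells (reversed). Log2 ratios were 0.14 for Ltbp4 in T cell-like cells (reversed) and 0.023 for Fbxl7 in T cell-like cells (reversed). At least 2-fold higher were 10 in fibroblast-like cells, 12 in mural-like cells and 45 in neutrophil-like cells. Past 2-fold lower, the genes numbered 12 in T cell-like cells, 93 in B cell-like cells, 14 in astrocyte-like cells, 5 in endothelial-like cells, 6 in fibroblast-like cells, 55 in monocyte-like cells, 11 in mural-like cells and 169 in neutrophil-like cells. Other classes with a median past the list threshold as higher numbered 3 for MHC class I presentation, 0 for T cell costimulation and adhesion, 0 for complement and Fc receptors, 0 for lysosome and phagocytosis, 0 for inhibitory receptors of myeloid cells, 0 for TGFb and IL10 and 1 for cell cycle. Medians past the list threshold as lower were found in other classes in 2 for CD200R signalling, 2 for chemokines, 2 for inhibitory receptors of myeloid cells and 1 for cell cycle.

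Among genes with at least 200 UMIs, genes at least 2-fold higher numbered 8 in T cell-like cells, 16 in B cell-like cells, 16 in ependymal or choroid plexus-like cells, 22 in fibroblast-like cells, 42 in monocyte-like cells and 38 in neutrophil-like cells. Genes at least 2-fold lower numbered 12 in T cell-like cells, 35 in B cell-like cells, 15 in astrocyte-like cells, 2 in ependymal or choroid plexus-like cells, 13 in fibroblast-like cells, 13 in monocyte-like cells and 58 in neutrophil-like cells.

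In core sub-clusters alone, the share ratio was 1.31 for CNS-associated macrophage-like cells. For CNS-associated macrophage-like cells, list medians stood at 0.10 for MHC class II presentation, -0.16 for immediate-early genes, -0.10 for core macrophage genes, 0.050 for complement and Fc receptors, -0.065 for lysosome and phagocytosis, 0.15 for oxidative phosphorylation, 0.011 for glycolysis and hypoxia (reversed), -0.080 for TGFb and IL10 and 0.44 for cell cycle. For T cell-like cells, list medians stood at 0.79 for MHC class II presentation, -0.18 for chemokines (reversed), 0.22 for complement and Fc receptors and -0.19 for cytotoxic effectors. Members higher numbered 3 of chemokines in T cell-like cells (reversed). Log2 ratios were 0.011 for Mmp12 in CNS-associated macrophage-like cells (reversed), 0.063 for Pdgfd in T cell-like cells (reversed), 0.29 for Ltbp4 in T cell-like cells (reversed), 0.36 for Mgp in T cell-like cells (reversed), 0.30 for Nebl in T cell-like cells (reversed), 0.17 for Fbxl7 in T cell-like cells (reversed) and 0.063 for Ccdc85a in T cell-like cells (reversed). The genes 2-fold lower numbered 13 in T cell-like cells. This setting was chosen after seeing the data.

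With the low-UMI cluster counted as microglia, the share ratio was 0.970 for microglia-like cells (reversed). For microglia-like cells, list medians stood at 0.033 for homeostatic genes. This setting was chosen after seeing the data.

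Among named immune cells, the share ratio was 0.983 for microglia-like cells (reversed) and 1.345 for CNS-associated macrophage-like cells. This setting was chosen after seeing the data.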

Other observations

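The lists and genes in this part were chosen after their values were seen. Glucocorticoid-induced genes had medians from -0.49 to -0.13 over the 11 classes, all lower in the library labelled KO, while core T cell sub-clusters had a median of 0.28. Genes linked to rRNA signal were lower in all 11 classes, with medians from -0.80 to -0.38. Among single genes, Lars2 ran from -1.01 to -0.62, Gm42418 from -0.88 to -0.38 and Cdk8 from -0.99 to -0.57. Npl ran from 0.51 to 1.41, higher in every class.

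Genes within 10 Mb of Cd200r1 were looked at in microglia-like, CNS-associated macrophage-like and endothelial-like cells. In microglia-like cells 3 of 74 (4.05%) were at least 1.5-fold apart, Parp14 (1.19), Parp9 (0.83) and Slc15a2 (-1.17), against 94 of 14023 elsewhere (0.670%). In CNS-associated macrophage-like cells 4 of 61 (6.56%) were, against 166 of 11320 (1.47%): Parp14 (0.84), Parp9 (0.66), Slc15a2 (-0.83) and Cd200 (-0.81). The Cd200 value stands beside endothelial markers at 457 and 245 CPM in this class, and in the core sub-clusters its interval of 0.371 to 1.16 includes no difference. In endothelial-like cells 2 of 70 (2.86%) were, against 133 of 13091 (1.02%). Slc15a2, at 36750177 to 36784962 on chromosome 16, had 604 and 53 UMIs in microglia-like cells of the libraries labelled WT and KO. Parp14 and Parp9 respond to interferon, and without them Slc15a2 alone remains in microglia-like cells, so the counts near Cd200r1 rest partly on the interferon difference. A linked difference was not tested.

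The interferon-inducible genes Ifi203, Mndal and Ifi213 were lower in endothelial-like cells (-1.20, -1.20 and -1.24) and higher in monocyte-like cells (1.46, 0.98 and 2.72). Microglia-like sub-clusters 2 (1040 and 265 cells), with Hspa1b and Fkbp5 among its leading genes, and 6 (120 and 2 cells) came mostly from the library labelled WT. Sub-cluster 3, led by interferon genes, came mostly from the library labelled KO (91 and 933 cells). At resolution 1 for states, sub-cluster 8 (314 and 25 cells) was led by Zbtb16 and Cables1, with Fkbp5 and Klf4 among its leading genes. Both libraries were clustered without integration, and interferon genes, Fkbp5 and Zbtb16 differ between them. Splits of sub-clusters with these among their leading genes are thus no further evidence of a difference.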
